A study of Mus musculus with 14 samples.

How the data were processed

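Gene expression was measured on 14 single-channel Affymetrix mouse arrays, 1 per sample of sorted T cells. Per the labels' protocols, cells were sorted by flow cytometry, RNA was purified with TRIzol and a silica column, and a whole-transcript kit turned 300 ng of total RNA into biotin-labelled sense-strand cDNA. The deposited values are log2 expression values per probe set made by the authors with RMA, per the submitters' processing notes. RMA corrects the background, normalizes arrays to each other by quantiles and summarises the probes of each probe set. The software that ran it, its version, the genome build behind the probe sets and whether all 14 arrays were normalized together are not given in the sources used here. The values could not be checked against scanner intensities, which were not used here.

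The table held 28213 probe sets. The platform annotation gave 1 gene symbol for 21640 of them, several for 1321 and none in the table used for 5252. Symbols were looked up by gene ID in a RefSeq gene table of the GRCm38.p6 assembly, which found 21553 of the 21640 and changed 0 symbols. That table served only for names, chromosomes and gene order, and no coordinates are given because the build behind the arrays is not known. For each of the 19937 symbols the probe set with the highest mean over all arrays was kept, which mattered for the 954 genes with several. Probe sets with several symbols or none were left out of the tests, and predicted genes were counted but not named. Genes were tested if they exceeded the 40th percentile of all values (6.76) on at least 2 arrays, which left 13641 genes.

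Samples were grouped by the labels into thymus CD4+CD8+ WT (n = 3), thymus CD4+CD8+ ENK KO (n = 2), spleen CD8+ WT (n = 4) and spleen CD8+ ENK KO (n = 5). No replicate number occurred in more than 1 group, so no samples were paired. The labels give each sample a number, an age and a sex but do not state outright that each came from a separate animal, so p-values measure the spread between these samples. No scan date or other batch label was used here.

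All 14 arrays entered 1 linear model with a mean per group in limma 3.58.1 under R 4.3.3, with moderated variances that follow the mean level (eBayes with a trend). The groups share 1 estimate of the spread because the thymus ENK KO group has 2 arrays. The comparisons were ENK KO minus WT in each tissue, the spleen effect minus the thymus effect, and WT spleen CD8+ minus WT thymus CD4+CD8+. P-values were adjusted by Benjamini-Hochberg over all genes tested, and an adjusted p under 0.05 counted as changed. Single values of En2, En1 and Penk, and the list means per array, were compared by exact two-sided permutation tests. Those of the list means were adjusted over the lists within each tissue.

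Of 35 gene lists (pathways, cell type markers and complexes, 674 genes, 557 of them tested), 33 were tested with camera from limma, with a preset correlation between genes of 0.01. Each list call was repeated with a correlation estimated per list and with fry, a rotation test of whether the genes of a list move, on balance, one way. P-values of lists were adjusted over the 33 lists. Counts described as adjusted over the list alone use Benjamini-Hochberg within that list. A list of sex-linked genes and one of the genes that the name ENK could stand for served as checks only.

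The groups, the tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. By that rule, each genotype comparison names the 10 genes with the largest difference in each direction among those past the threshold whose ENK KO arrays all lay on the same side of the WT mean. Where fewer than 10 passed, the remaining places were filled by the smallest unadjusted p, and values of such genes are given without calling them changed. The comparison of WT populations names the 10 largest differences in each direction, and each list described names up to 4 members with the smallest p. En2, En1 and Penk were always named. Genes outside the rule are said to have been chosen after their values were seen.

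The alternatives were no filter, a filter at the 60th percentile (9470 genes), quantile normalization or median centring of the deposited values, the mean of a gene's probe sets, every probe set on its own, variance models without a trend or with robust estimation, array weights, a fit of each tissue alone, sex and an age of 2 months as covariates, no 2-month-old animals, males only, each array left out in turn, and an unadjusted p under 0.05 with a fold of at least 1.5. Fits without both the library labelled spleen ENK KO replicate 28 and spleen WT replicate 22, a fit of spleen arrays alone without replicate 28, a sex covariate without replicate 22, and all alternatives for the lists of the difference between tissues, were added after seeing the data.

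The steps were tested on simulated data with 200 of the 13641 genes changed at known sizes. With a log2 difference of 1, 95.0% of them were recovered in the thymus design, 98.0% in the spleen design and 96.5% in the design of WT populations, with 14, 7 and 13 false calls. With a log2 difference of 0.5 the recovered shares were 73.0%, 88.5% and 89.0%. A simulated list of 24 genes shifted by 0.3 had an unadjusted camera p under 0.05 in 20 of 20 runs in both genotype comparisons. An unshifted list had one in 0 of 20. The simulated genes varied independently of each other, so these runs do not show how often camera calls lists of genes that vary together. Each simulated gene also had the same spread in all groups. With 200 changed genes an adjusted p under 0.05 is easier to reach than with a few. The recovered shares may therefore be too high for these data. Array data give no counts, so the number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.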

Results

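Gene expression was measured in sorted T cells of mice labelled wild type (WT) or ENK KO. Thymocytes carrying both CD4 and CD8, an immature stage at which the T cell receptor alpha chain is rearranged, came from the thymus (WT, n = 3; ENK KO, n = 2). CD8+ T cells, the lineage of cytotoxic T cells, came from the spleen (WT, n = 4; ENK KO, n = 5). The design asks how ENK KO mice differ from WT mice in each of these populations. The labels do not spell out ENK, and the series title names Engrailed-2, a homeobox transcription factor encoded by En2. WT animals were all 7 months old. In the thymus comparison 1 of the 2 ENK KO animals was 2 months old, and in the spleen comparison 2 of 5 were. The oldest was 9 months old, so that genotype and age overlapped in part. Each 2-month-old animal was labelled female, and no other ENK KO animal was, so that age and sex coincided within ENK KO. Leaving out the 2-month-old animals and keeping males only therefore kept the same ENK KO arrays. Each WT group held 1 array labelled female. The median log2 value per array lay between 7.14 and 7.25, and the first principal component, with 85.9% of the variance, separated thymus from spleen arrays.

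En2 was near the low end of the signal in both populations and did not differ detectably between genotypes. In thymus the mean log2 value was 6.01 ± 0 (SD, n = 3) in WT and 6.07 ± 0.09 (n = 2) in ENK KO, a difference of 0.065 (exact two-sided permutation p = 0.4; 3 arrays against 2 cannot give less than 0.1). In spleen it was 6.49 ± 0.32 (n = 4) in WT and 6.71 ± 0.69 (n = 5) in ENK KO, a difference of 0.22 (exact two-sided permutation p = 0.683). That difference turned to -0.067 without ENK KO replicate 31, the highest array at 7.87. The WT means stood at the 22.7th and 33.5th percentile of all values. Its paralogue En1 differed by -0.16 in thymus and 0.034 in spleen (exact permutation p = 0.3 and 0.54). Single arrays moved these values, from -0.24 without ENK KO replicate 29 to -0.075 without ENK KO replicate 1 in thymus and from 0.0027 without WT replicate 34 to 0.083 without WT replicate 40 in spleen. Penk, the proenkephalin gene, differed by -0.034 and 0.064 (exact permutation p = 0.3 and 0.841). The position of these probes relative to any deleted part is not given in the sources used here, and a probe outside it checks nothing, so the arrays neither bear out nor contradict the genotype labels. Among homeobox partners and paralogues of engrailed, 12 genes were tested, and limma called 0 in either tissue over all genes and 0 adjusted over the list alone, with 0 in thymus and 3 in spleen at an unadjusted p under 0.05. Camera gave this list an adjusted p of 0.302 in thymus and 0.351 in spleen. For 13 transcription factors of T cell leukaemia, a group linked to the disease in the series title, camera gave 0.91 and 0.832.

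Cd4, Cd8a and Cd8b1 followed the sorted populations on 13 of the 14 arrays. The exception was the library labelled spleen ENK KO replicate 28, where Cd4, the co-receptor of helper T cells, was at 12.20, against 6.61 to 6.92 on the other spleen arrays. Cd8a and Cd8b1, the chains of the CD8 co-receptor, were at 6.78 and 9.10, against at least 12.06 and 13.20. Foxp3, the transcription factor of regulatory T cells, was at 9.87 against at most 7.48, and Il2ra, a chain of the interleukin-2 receptor, at 11.14 against at most 7.12. Foxp3 and Il2ra were singled out after their values were seen. This array also stood apart on the second principal component (3.46% of the variance) at 27.5, the other 13 lying between -11.8 and 3.05. The calls of genes and lists in spleen are therefore also given without it. Spleen values of genes and lists that did not pass are given with it unless stated. Spleen WT replicate 22, labelled female, had Xist, the transcript of the inactive X chromosome, at 5.90, against 12.36 to 13.37 on the other 4 arrays labelled female. Its Y-linked genes Kdm5d, Uty and Eif2s3y were at 9.85, 9.69 and 10.17. Unless stated, fits with a sex covariate counted this array as female, and fits of males only left it out. If its sex label is wrong, the only females among the spleen arrays were the 2-month-old ENK KO animals, replicates 3 and 6. Sex, age and genotype would then overlap in spleen, and the fits with a sex covariate would rest on a wrong sex for this array.

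**Figure D1:**
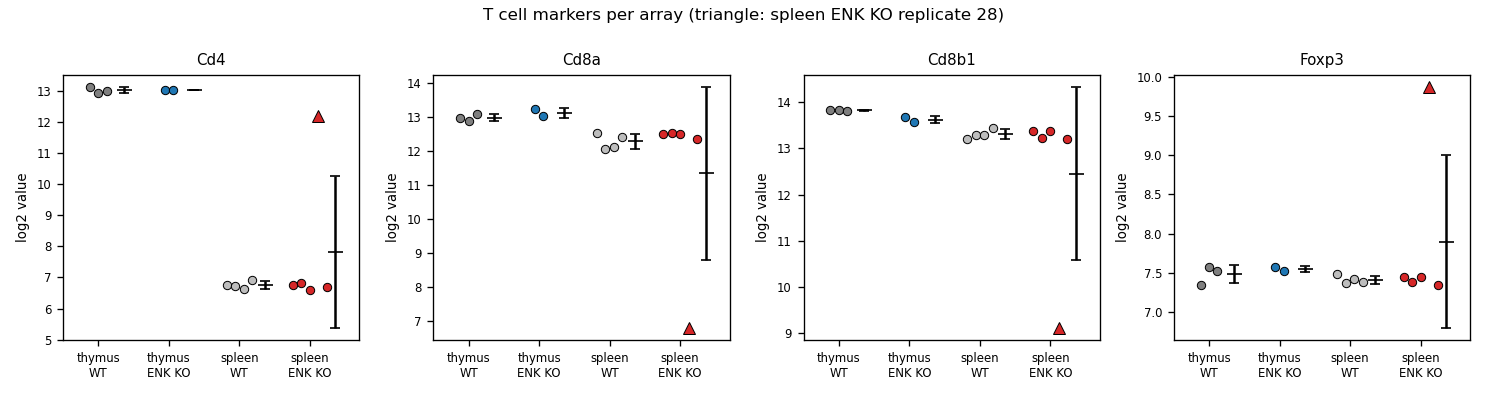
Log2 values of marker genes on each array (points, by group; bars show the mean ± SD). The library labelled spleen ENK KO replicate 28 (triangle) lay at 12.20 for Cd4 and 6.78 for Cd8a, apart from the other spleen arrays.

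The WT populations differed widely. Spleen CD8+ cells had far more mRNA of genes of mature, circulating T cells: Dapl1, a marker of naive T cells, was 157-fold higher than in thymocytes (log2 difference 7.29, SE 0.11), and Il7r, the interleukin-7 receptor, 122-fold (6.93, SE 0.14). S1pr1, the receptor with which T cells leave lymphoid organs, was 48.0-fold higher. Genes of cytotoxic and memory cells were higher too, among them Nkg7 (109-fold), the chemokine gene Ccl5 (42.6-fold), Klrd1 (56.1-fold) and Il2rb (53.1-fold), as were Cd55, Ms4a4c and Samhd1 (76.4-, 64.7- and 41.1-fold). Thymocytes had more of the machinery of receptor gene rearrangement: Rag1 and Rag2, the recombinase genes, differed by -6.64 (SE 0.10) and -6.46 (SE 0.12), and Dntt, which adds nucleotides at the joints, by -5.82 (SE 0.09). Arpp21, Cd4, Aqp11, Plxdc2, Dhrs3, Slc7a11 and the probe set named Mir181b-1 were also lower in spleen, by log2 differences of -5.01 to -6.70. In 9 of the 10 genes higher and 8 of the 10 genes lower in spleen, the lower group lay under the filter level of 6.76, where signal is hard to tell from background, so that these folds and their order are approximate. By limma 9362 of 13641 genes (68.6%) differed, 4157 higher and 5205 lower in spleen CD8+ cells, the largest adjusted p among the genes named being 0.000157 for Cd4. An unadjusted p under 0.05 with a fold of at least 1.5 gave 3756 genes. Whether thymus and spleen arrays were normalized together is not given, which also limits these folds and counts.

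Gene lists differed as well. Of 24 mitotic genes all 24 were lower in spleen CD8+ cells, for example Kif11 (-3.19) and Bub1 (-2.47), and of 27 DNA replication genes 16 were lower and 1 higher, among them Gins1 (-1.26) and E2f1 (-1.15). Camera gave adjusted p = 1.70e-08 and 0.00368, and adjusted p = 0.391 and 0.531 with an estimated correlation. Of 21 genes of CD4+CD8+ thymocytes 16 were lower and 2 higher (adjusted p = 2.00e-06), the only 1 of 15 list calls to hold with an estimated correlation (adjusted p = 0.0165), while fry called 28 of 33 lists (smallest adjusted p = 4.15e-15). Naive T cell genes were mostly higher, 12 of 16 with 2 lower, Dapl1 and Il7r leading and Il6ra at 4.08 (adjusted p = 4.50e-06; adjusted p = 0.254 with an estimated correlation). Effector and memory CD8 genes were higher in 28 of 36 and lower in 3, with Il18r1 at 5.02 and Anxa2, a membrane-binding annexin, at -2.84 (adjusted p = 1.73e-06; adjusted p = 0.431 with an estimated correlation). Type I interferon response genes were higher in 25 of 27 and lower in 1, for example Ddx58 (1.36) and Irf9 (1.31), and MHC class I presentation genes in 11 of 13, for example B2m (1.15) and Psme2 (2.21). Their adjusted p was 3.44e-07 and 2.00e-06, and adjusted p = 0.426 and 0.108 with an estimated correlation. Adjusted over the list alone, the interferon list had 26 genes higher, and the counts of the other lists in this paragraph did not move.

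In CD4+CD8+ thymocytes, Slc7a11, the cystine-glutamate exchanger subunit that supplies cystine for glutathione synthesis, rose 2.45-fold in ENK KO. Its mean log2 value went from 10.66 ± 0.23 (SD, n = 3) to 11.96 ± 0.29 (n = 2), a difference of 1.29 (SE 0.14, adjusted p = 0.00843). Srpk2, a kinase of serine/arginine-rich splicing factors, rose 2.20-fold, from 9.63 ± 0.02 to 10.77 ± 0.50 (difference 1.14, SE 0.14, adjusted p = 0.0179). The ENK KO arrays stood at 10.42 and 11.12 for Srpk2, above the highest WT array at 9.66. Limma called no gene lower. At an unadjusted p under 0.05 there were 481 genes, 245 higher and 236 lower, against 682 expected by chance.

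Among the genes filled in by the smallest unadjusted p, which did not pass the threshold, several act in cell division. Bub1, a kinase of the spindle checkpoint, differed by 0.70 (SE 0.15; 0.41 without ENK KO replicate 29), the spindle protein gene Nusap1 by 0.84 (SE 0.19), Dlgap5 by 0.39 and Ckap2 by 0.35. Ankrd50, S100a11, Sipa1l1 and Noct differed by 0.50, 0.64, 0.66 and 0.31, the last by 0.19 without ENK KO replicate 1. On the lower side Gnb4, a G protein beta subunit, differed by -1.45 (SE 0.26), Plekhf1 by -1.20, Cd1d2, a lipid-presenting molecule, by -0.92, and Car2, a carbonic anhydrase, by -0.87. Agtrap, Fbxo44, Yaf2, Glipr1, Rit1 and Rxfp1 differed by -0.77 to -0.43. Their adjusted p ran from 0.0691 (Agtrap) to 0.487 (Nusap1).

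Both calls rest on the spread shared with the spleen arrays: with thymus arrays alone limma called 0 genes (339 at an unadjusted p under 0.05), and Slc7a11 and Srpk2 had adjusted p = 0.869. Males only and sex and age together as covariates also left 0 genes (473 and 499 at an unadjusted p under 0.05), while the log2 difference of Slc7a11 was 1.52 and 1.35 and that of Srpk2 0.80 and 1.09. With age alone Srpk2 had adjusted p = 0.104 at 1.07. Srpk2 lost its call without WT replicate 7 (adjusted p = 0.0645) or WT replicate 32 (0.0852), while the count was 1 without WT replicate 32, 13 without WT replicate 38, 14 without ENK KO replicate 29 and 4 without ENK KO replicate 1. Over all alternatives the adjusted p ran from 0.00336 to 0.869 for Slc7a11 and from 6.46e-06 to 0.869 for Srpk2.

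**Figure D2:**
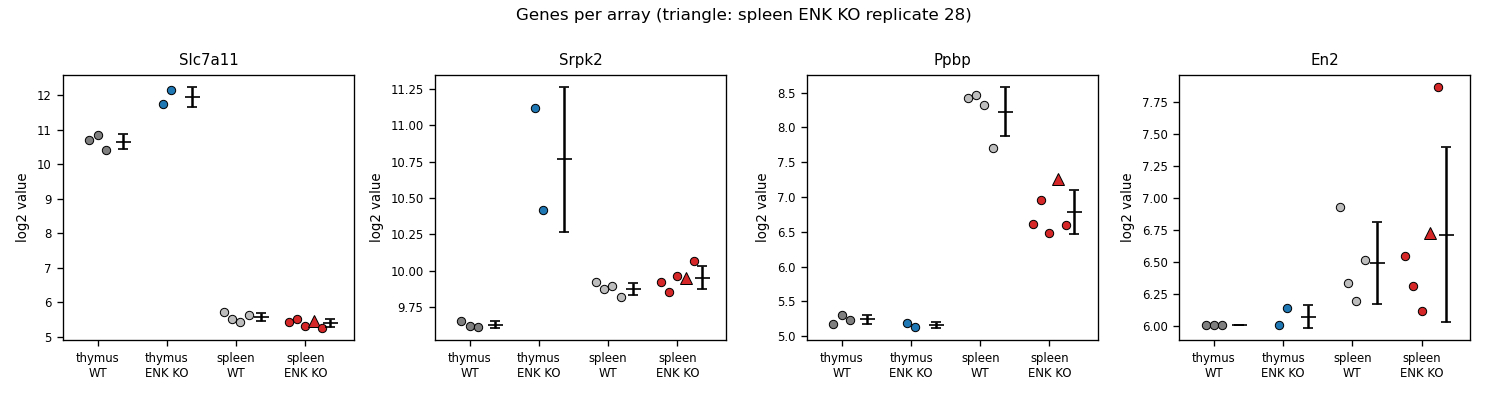
Log2 values of Slc7a11, Srpk2, Ppbp and En2 on each array (points, by group; bars show the mean ± SD; the triangle is the library labelled spleen ENK KO replicate 28). In thymus both ENK KO arrays lay above all WT arrays for Slc7a11 and Srpk2, and in spleen all 5 ENK KO arrays lay below the WT arrays for Ppbp.

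As a group, mitotic genes were higher on the 2 ENK KO thymus arrays. The log2 difference was above 0 for 23 of 24, with a mean of 0.38, and led by Bub1, Nusap1, Ncapg (0.58) and Cdk1 (0.61), the kinase that drives entry into mitosis. None passed over all genes, 17 were higher at an unadjusted p under 0.05 in limma, and 15 were higher adjusted over the list alone. Camera gave adjusted p = 4.90e-30, and adjusted p = 0.0528 with an estimated correlation, while fry gave 0.108. The list mean was 8.76 on the 7-month-old ENK KO array and 8.52 on the 2-month-old one, against 8.06 to 8.45 on the WT arrays. An exact two-sided permutation test of these array means gave p = 0.2 (adjusted 0.825), where the smallest possible p is 0.1. DNA replication genes were higher in 24 of 27 with a mean of 0.25, which was 0.13 without ENK KO replicate 29, among them Tyms (0.49), Pola1 (0.52), Rrm2 (0.79) and Chaf1a (0.25). None of them passed over all genes, 12 did so at an unadjusted p under 0.05, and 3 were higher adjusted over the list alone (camera adjusted p = 1.08e-20; adjusted p = 0.0528 with an estimated correlation; fry 0.108). The replication list mean was 9.10 on the 7-month-old ENK KO array and 8.86 on the 2-month-old one, against 8.66 to 8.82 on the WT arrays. The exact permutation test of these means gave p = 0.1 (adjusted 0.66). Both lists kept their calls without any one thymus array, the largest adjusted p being 1.84e-09 and 0.00158.

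The calls of a pair of other lists depended on single arrays. Heat shock and unfolded protein genes were higher in 11 of 17 by a mean of 0.29, with Hsp90aa1 at 0.83, Hspa8 at 0.27, Hspd1 at 0.57 and Hspe1 at 0.39 (camera adjusted p = 0.00421; adjusted p = 0.793 with an estimated correlation). Notch pathway genes were higher in 12 of 17 by a mean of 0.12 (adjusted p = 0.0151; adjusted p = 0.13 with an estimated correlation), led by Ptcra, the invariant chain of the pre-T cell receptor (0.47), Notch3 (0.27), Dtx1 (0.38) and Notch2 (0.10). In limma no member of either list passed over all genes, 2 of each list did at an unadjusted p under 0.05, and Ptcra did adjusted over the list alone (0.0218). The heat shock call was lost without WT replicate 7 (0.11) or ENK KO replicate 1 (0.0612), and the Notch call without WT replicate 7 (0.091), WT replicate 32 (0.0718) or ENK KO replicate 1 (0.0612). The heat shock mean was 0.27 and 0.40 in these fits, and 0.18 without ENK KO replicate 29. The Notch mean was 0.14, 0.10 and 0.095 in the fits named for it. Both calls were also lost without the 2-month-old animals (0.114 each) and in males only (0.359 and 0.235). Genes of CD4+CD8+ thymocytes as a list did not differ, with 11 above and 10 below 0 (adjusted p = 0.519), and early thymocyte markers were above 0 in 9 of 11 (adjusted p = 0.185, but 0.0371 without WT replicate 38 and 0.0201 without both spleen replicates 28 and 22). No list of B cell, myeloid, antigen presenting, NK, erythroid or stromal markers passed in thymus, their adjusted p being at least 0.358. Adjusted over the list alone, Ptcra passed among the CD4+CD8+ thymocyte genes (0.0269) and Car2, lower, among the NK markers (0.00219). For the B cell and stromal lists camera pointed up while the mean was -0.0022 and -0.035, and for the antigen presenting list it pointed down while the mean was 0.0019.

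The thymus genes with the smallest p lay more often on chromosome 3 than elsewhere. Of 25 genes with an unadjusted p under 0.001, 10 were on chromosome 3 in the GRCm38.p6 gene table, where 598 of the 13633 placed genes lay and 1.10 were expected, a 9.12-fold excess. Slc7a11, Ankrd50, Noct and S100a11 were higher, while Gnb4, Rxfp1, Cd1d2, Rit1, Car2 and Gpr89 were lower. Gpr89 and this grouping by chromosome were chosen after the values were seen. In spleen 0 of 21 such genes lay there, and 1 of 23 without the library labelled spleen ENK KO replicate 28 (1.01 expected).

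**Figure D3:**
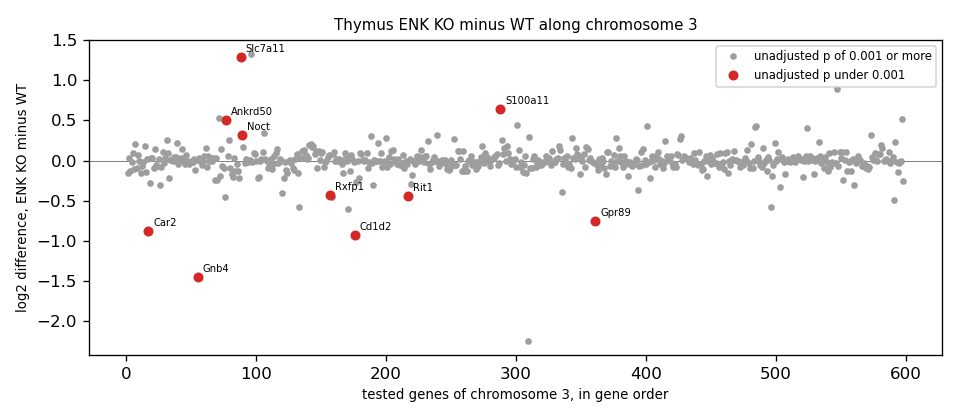
ENK KO minus WT log2 differences in thymus of the tested genes of chromosome 3, in gene order (1 point per gene). The 10 genes with an unadjusted p under 0.001 are named; 4 lie above 0 and 6 below.

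In spleen CD8+ cells Ppbp, a chemokine gene of platelets, fell in ENK KO. Its mean log2 value went from 8.23 ± 0.36 (SD, n = 4) to 6.78 ± 0.32 (n = 5), a 2.72-fold difference (log2 -1.44, SE 0.17, adjusted p = 0.0215), and the highest ENK KO array (7.26) lay below the lowest WT array (7.70). Without the library labelled spleen ENK KO replicate 28, Ppbp differed by -1.56 (SE 0.15, adjusted p = 0.00377). Irak3, an inhibitor of Toll-like receptor signalling, then differed by -0.67 (SE 0.07, adjusted p = 0.00534); it was at 9.74 in that library, against 6.91 to 7.13 on the other ENK KO arrays, and was chosen after its values were seen. Limma called no gene higher. At an unadjusted p under 0.05 there were 1142 genes, 470 higher and 672 lower, against 682 expected by chance, and 1326 without that library. Spleen arrays alone gave 792, so the size of the excess depends on whether the spread is shared. Pairs of arrays correlated at 0.988 to 0.994 in thymus and at 0.970 to 0.993 in spleen. A shared spread may thus be too small for spleen and too large for thymus.

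The genes filled in by the smallest unadjusted p differed by small amounts. Ezh2, the histone methyltransferase of Polycomb complexes, differed by 0.38 (SE 0.09), Cdk2, a kinase of the cell cycle, by 0.40 (SE 0.08), and Nek3 by 0.43 (SE 0.08). Spopl, Ppm1b, Smap1, Asxl1, Ncln, Fbxl17 and Hint3 differed by 0.16 to 0.24. On the lower side Irf8, a transcription factor of dendritic and B cells, differed by -0.29 (SE 0.06), Fgfr1 by -0.42, Igkv4-55, an immunoglobulin gene segment, by -0.40, Nrgn by -0.27 and Coro1c by -0.21. Snrpa, Tmem141, Tpbgl and Lancl3 differed by -0.20, -0.27, -0.32 and -0.33. Their adjusted p ran from 0.317 (Nrgn) to 0.553.

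The Ppbp call was a narrow one. It was lost without ENK KO replicates 6 (adjusted p = 0.0629), 25 (0.0875) or 3 (0.112), without WT replicates 37 (0.164), 34 (0.095) or 22 (0.0847), and without any one of the 5 thymus arrays (0.0552 to 0.0594). The gene count was then 0, against 3 without ENK KO replicate 31 and 2 without replicate 28. Spleen arrays alone gave 0 genes (Ppbp 0.445; 792 genes at an unadjusted p under 0.05), as did sex (0.053; 1040), an age of 2 months (0.121; 971) or both as covariates (0.197; 1061) and males only (0.755; 775), and without the 2-month-old animals Ppbp had adjusted p = 0.342. Its log2 difference in these fits was -1.45 with sex or age, -1.43 with both, -1.38 in males and -1.44 without the 2-month-old animals, close to the -1.44 of all arrays. Over all alternatives the adjusted p ran from 0.000987 to 0.755.

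Erythroid and platelet markers were lower as a group in ENK KO spleen samples, all 10 with a difference below 0. Beside Ppbp, Slc4a1, the anion exchanger of red cells, differed by -0.40, Gp9, a platelet glycoprotein, by -0.12, and Car1 by -0.40. Over all genes 1 passed, at an unadjusted p under 0.05 there were 4, and 2 were lower adjusted over the list alone (Ppbp and Slc4a1). Camera gave adjusted p = 0.000337, and adjusted p = 0.241 with an estimated correlation, and fry 0.0224. Without replicate 28 camera gave 0.00229, while the fry call was lost (0.0597).

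Markers of B cells and of antigen presenting cells, which a CD8 sort should leave out, were lower as well. Of 16 B cell and plasma cell markers 15 were below 0, with Cd79a, part of the B cell receptor, at -0.62, Ms4a1 at -0.54, Cd22 at -0.39 and Pou2af1 at -0.13 (camera adjusted p = 0.000337; adjusted p = 0.839 with an estimated correlation; 0.00368 without replicate 28). Of 13 antigen presenting cell markers 10 were below 0, with the MHC class II genes H2-Aa and Cd74 at -0.59 and -0.54, Irf8 at -0.29 and Bst2 at -0.19 (0.00601; adjusted p = 0.839 with an estimated correlation; 0.00699 without replicate 28). Irf8 was lower adjusted over the list alone (0.00749), no B cell marker was, and in limma no member of either list passed over all genes, with 4 B cell and 2 antigen presenting cell markers at an unadjusted p under 0.05. The antigen presenting call was lost without ENK KO replicate 25 (0.0812) or WT replicate 22 (0.114), and both calls were lost without replicates 28 and 22 together (B cell 0.0659, antigen presenting 0.0842). The mean of the B cell list was -0.23, and -0.15 without ENK KO replicate 25 and -0.36 without ENK KO replicate 6.

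Effector and memory CD8 genes were lower in ENK KO in 31 of 36, with a mean of -0.35. Klrc1, a natural killer receptor, was at -1.41 (SE 0.48), Anxa2 at -0.58, S100a6 at -0.55 and Il18r1, an interleukin-18 receptor chain, at -0.27 (adjusted p = 0.000424; adjusted p = 0.839 with an estimated correlation). These values of single genes include replicate 28. Without replicate 28 the mean was -0.20 (0.0131), and without WT replicate 37 the call was lost (0.0981). The call was kept without the 2-month-old animals (0.00675) and in males only (0.00654), but both fits keep replicate 28. The fits without replicate 28 keep 2-month-old ENK KO animals, while all WT animals were 7 months old. No fit left out both, so an effect of genotype on this list cannot be told apart from age and that array. Immediate early and activation genes were lower in 24 of 26, among them Cd69 (-0.68), Fos (-0.67), Zfp36 (-0.38) and Nfkbia (-0.29), with adjusted p = 0.00546, and adjusted p = 0.839 with an estimated correlation. Without replicate 28 it was 0.00229. That call was lost without ENK KO replicates 6 (0.131) or 3 (0.0881) or WT replicates 37 (0.335) or 34 (0.0799), and without both 2-month-old animals the direction turned upward (0.927). In males only, a fit that keeps the same ENK KO arrays, replicate 28 among them, the adjusted p was 0.69. In limma no member of either list passed over all genes or adjusted over the list alone, with 7 effector and memory genes and 0 immediate early genes at an unadjusted p under 0.05.

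Respiratory complex I genes were lower in 29 of 35 by a mean of -0.065, with Ndufb10 at -0.18 and Ndufa12 at 0.10 (adjusted p = 0.0102; adjusted p = 0.839 with an estimated correlation; 0.0471 without replicate 28). This call was lost without ENK KO replicates 6 (0.0629) or 25 (0.0735) or WT replicate 37 (0.0635), or without replicates 28 and 22 together (0.106). All 5 tested opioid peptide and receptor genes were below 0, with Pdyn at -0.21, Oprd1, the enkephalin receptor gene, at -0.17, Ogfr at -0.091 and Pomc at -0.074 (0.0121; adjusted p = 0.554 with an estimated correlation; 0.0332 without replicate 28). The opioid call was lost without the 2-month-old animals (0.0879), in males only (0.177) and without replicates 28 and 22 together (0.0659). In thymus camera gave the opioid list an adjusted p of 0.983 and pointed up, while its mean was -0.0053. In limma no member of these lists passed over all genes or adjusted over the list alone, with 3 and 2 at an unadjusted p under 0.05. In all, 7 lists were called in spleen, 4 without WT replicate 37 and 10 without replicate 28. Exact permutation tests of the list means per array passed no spleen list, the smallest adjusted p being 0.524. Of 100 splits of the 9 spleen arrays into groups of 4 and 5, the real one included, 17 gave at least as many genes and 47 at least as many lists as the real one.

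**Figure D4:**
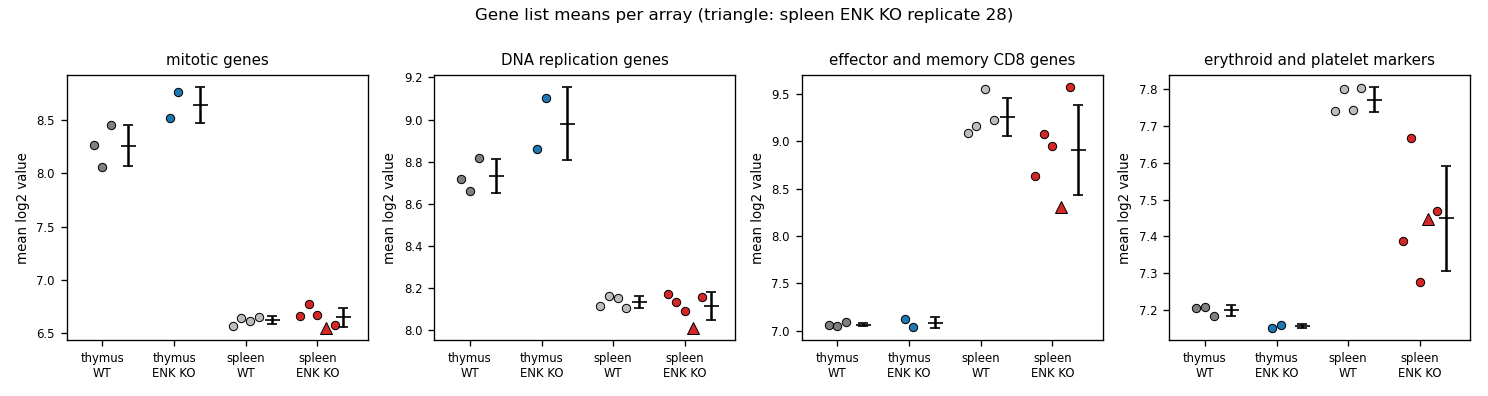
Mean log2 value of gene lists on each array (points, by group; bars show the mean ± SD; the triangle is the library labelled spleen ENK KO replicate 28). The mitotic list lay at 8.52 and 8.76 in thymus ENK KO and at 8.06 to 8.45 in thymus WT.

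The effect of ENK KO was then compared between the populations. Slc7a11 passed, with a log2 value of -1.47 for the spleen effect minus the thymus effect (adjusted p = 0.0218). It was at 5.58 ± 0.12 (SD, n = 4) in spleen WT and 5.40 ± 0.11 (n = 5) in spleen ENK KO, under the filter level of 6.76, where a genotype effect could hardly be measured, so that this value restates the thymus result. At an unadjusted p under 0.05 limma gave 408 genes, against 682 expected by chance. The Slc7a11 call was lost, leaving 0 genes, without thymus WT replicate 7, spleen ENK KO replicates 31, 25 or 3, or spleen WT replicates 40, 34 or 22, and the count was 5 without thymus ENK KO replicate 29, 4 without thymus ENK KO replicate 1 and 2 without thymus WT replicate 38. Over all alternatives the adjusted p of Slc7a11 in this comparison ran from 0.0114 to 0.388.

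As a list, mitotic genes differed between the populations, the spleen effect being below the thymus effect in 23 of 24, as did DNA replication genes, with 26 of 27 below (12 and 10 at an unadjusted p under 0.05, and none over all genes in limma; camera adjusted p = 1.34e-14 and 9.08e-14; adjusted p = 0.317 with an estimated correlation for both). Without the library labelled spleen ENK KO replicate 28 the adjusted p was 1.43e-10 and 1.69e-10. Only 10 of the 24 mitotic genes exceeded the filter level in spleen, and of these 9 were lower, by a mean over the 10 of -0.29, while the others, Bub1 and Nusap1 among them, lay under it. Of the DNA replication genes 25 exceeded it. The B cell (0.00423) and erythroid and platelet (0.0136) lists were lower in spleen relative to thymus, with 0.0159 and 0.0282 without replicate 28, as were the effector and memory (0.00423; 0.0159) and immediate early (0.00948; 0.00303) lists. The mean of the effector and memory list was -0.37, and -0.22 without replicate 28. In thymus only 14 of 36 effector and memory genes, 7 of 16 B cell and 7 of 10 erythroid and platelet markers exceeded the filter level, so that these differences largely restate the spleen result. Over the members above it in both tissues the means were -0.22, -0.14 and -0.15, against -0.37, -0.23 and -0.28 over all members. T lineage transcription factors, with Hivep3 at 0.20 and Bach2 at 0.20, were higher (0.0229) by a mean of 0.10, but not without replicate 28 (0.064, adjusted p = 0.0823). With an estimated correlation none of these 5 passed, at adjusted p = 0.825, 0.336, 0.862, 0.88 and 0.814 in the order given. Adjusted over the list alone, 2 mitotic genes (Bub1 and Nusap1) and 1 erythroid and platelet marker (Ppbp) passed, but Bub1 and Nusap1 lay under the filter level in spleen and Ppbp (5.24 in WT and 5.16 in ENK KO) in thymus.

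Several of these list calls depended on other single arrays. The T lineage call was also lost without thymus ENK KO replicate 1 (0.589), thymus WT replicate 7 (0.188), spleen ENK KO replicate 25 (0.116) or spleen WT replicate 40 (0.0664). The immediate early call was lost without spleen WT replicates 37 (0.195) or 34 (0.0832), spleen ENK KO replicates 6 (0.0808) or 3 (0.0774), thymus WT replicate 32 (0.0913) or thymus ENK KO replicate 29 (0.0572). The effector and memory call was lost without spleen WT replicate 37 (0.10) or thymus ENK KO replicate 1 (0.0502), and the erythroid and platelet call without thymus ENK KO replicate 29 (0.0572). The mitotic, DNA replication and B cell lists kept their calls without any one array, the largest adjusted p being 8.32e-05, 0.00229 and 0.0437.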

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

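Of the tests of explanations in this part, that of the copy number of chromosome 3 was planned before its result was known, and the others were chosen only after the result was seen. Samples far from their group were looked for in 68 groups of values, each from the 4 spleen WT or the 5 spleen ENK KO arrays. The measure was the gap of the highest or lowest sample to its neighbour as a share of the range (Dixon's ratio). Thymus arrays were not checked in this way. This picked out 9 groups, where chance picks about 1 in 20. Of the 9, 5 are the values of Cd4, Cd8a, Cd8b1, Foxp3 and Il2ra in the library labelled spleen ENK KO replicate 28. These genes had already set that library apart when they were put into the check. The 5 thus restate that observation and cannot be set against the chance rate.

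In that library, Dixon's ratio was 0.964 for Cd4, 0.970 for Cd8a, 0.957 for Cd8b1, 0.959 for Foxp3 and 0.948 for Il2ra. A swap with a thymus array is argued against by its mean of the CD4+CD8+ thymocyte genes without Cd4, Cd8a and Cd8b1, 8.08 against 11.26 to 11.32 on thymus arrays, and a loss of Cd8a through the genotype by the other 4 spleen ENK KO arrays, the lowest of which was at 12.36 against 12.06 to 12.52 in WT. CD4+ T cells in place of CD8+ T cells are consistent with the values: 8 of 10 markers of regulatory and helper CD4 T cells (Cd4, Foxp3, Il2ra, Ikzf2, Zbtb7b, Tnfrsf4, Ctla4 and Tnfrsf18) lay above the highest of the other 8 spleen arrays, and 5 of 7 when Cd4, Foxp3 and Il2ra, which raised the question, are left out. The exceptions were Icos at 10.43 against 10.46 and Cxcr5 at 7.15 against 8.39. Whether another fraction of the sort was collected or a tube was mislabelled cannot be read from these values, and no biological explanation beyond genotype was tested.

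For the excess of chromosome 3 genes among the thymus differences, a changed copy number would move the whole chromosome. It is argued against by the median log2 difference of its 598 genes, 0 (95% bootstrap interval over genes -0.0023 to 0.0034). For a segment of another strain acting alike in both tissues, the 8 of the 10 genes expressed in spleen were used. The slope of their spleen on thymus differences was 0.10 (95% bootstrap interval -0.0019 to 0.257), where an equal effect would give 1. These genes were picked for a small thymus p, which tends to inflate their thymus differences. The interval also resamples genes and not animals, so the slope cannot decide the question. Chance placement of single genes gave an excess as large on any chromosome in a share of 1e-05, the smallest that 100000 placements can give, while shifting the differences along the gene order, which keeps neighbours together, gave one in a share of 0.104 of 1000 shifts, so that chance placement of runs of neighbours stays open. Both shares use the smallest binomial tail of any chromosome; the excess in standard units, used at first and replaced after its values were seen because single genes on the mitochondrial or Y chromosome led it, gave 0.0126 and 0.165. A segment of another strain that acts in thymocytes alone or is carried by some of the animals could not be tested and may also underlie the pattern.

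The higher mitotic and replication lists in ENK KO thymocytes may reflect the genotype, the age of 1 animal or the cells that passed the sort. The age of the 2-month-old animal alone would leave the 7-month-old ENK KO array among the WT arrays, and its mitotic list mean was 8.76 against 8.06 to 8.45, which is 1 array and leaves age open. More early thymocytes, which divide more than CD4+CD8+ thymocytes do on average, would raise their markers. The early thymocyte list differed by a mean of 0.14 (95% bootstrap interval over genes 0.035 to 0.277). Camera gave adjusted p = 0.185, and 0.0371 without WT replicate 38 and 0.0201 without both spleen replicates 28 and 22. The interval resamples genes and not animals, so it does not measure the spread between animals. An exact two-sided permutation test of the array means gave p = 0.2 (adjusted 0.825), where the smallest possible p is 0.1. These values leave this explanation open too. The 3 explanations cannot be told apart with 2 ENK KO arrays.

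In spleen WT replicate 22, labelled female but low in Xist, Dixon's ratio was 0.939 for Lancl3 and 0.854 for the mean of the antigen presenting cell markers. In spleen ENK KO replicate 31 it was 0.747 for Ezh2 and 0.725 for Snrpa.

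For Slc7a11 the test of the difference between the effects of ENK KO in spleen and thymus passed (log2 -1.47, adjusted p = 0.0218), both thymus ENK KO arrays lying above all 3 thymus WT arrays. All spleen arrays lay at 5.25 to 5.71, under the filter level of 6.76, so the value is no evidence of an effect that differs between populations. Camera gave a difference for mitotic genes (adjusted p = 1.34e-14, lower in spleen for 23 of 24; 10 of the 24 exceeded the filter level there) and DNA replication genes (9.08e-14, 26 of 27), for effector and memory CD8 genes (0.00423; 0.0159 without replicate 28), B cell markers (0.00423), immediate early genes (0.00948) and erythroid and platelet markers (0.0136), all lower in spleen. Of these, 14 of 36 effector and memory genes, 7 of 16 B cell and 7 of 10 erythroid and platelet markers exceeded the filter level in thymus. For T lineage transcription factors it gave 0.0229, higher in spleen in 14 of 19, and 0.0823 without replicate 28. None of these list differences passed with an estimated correlation (smallest adjusted p = 0.317) or with fry (0.409).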

How the results depend on the processing

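Some fits were chosen only after the result was seen: without both doubtful spleen arrays (ENK KO replicate 28 and WT replicate 22), with a sex covariate but without WT replicate 22, and of spleen arrays alone without replicate 28, as were the alternatives for lists of the difference. No paired analysis was possible because the groups share no replicate numbers, and the fit of a single tissue was not run for the comparisons that span both. The counts of genes (2 in thymus, 1 in spleen, 1 for the difference between them) stayed within 1.5-fold with either filter, both normalizations, both treatments of probe sets and both variance models.

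With array weights limma called 24 genes in thymus (2 shared) and 2 for the difference (1 shared). A sex covariate left 0 in spleen and 0 for the difference, an age covariate 1 in thymus, 0 in spleen and 0 for the difference, and both covariates, like males only, 0 in each of these. Without the 2-month-old animals there were 4 in thymus (2 shared), 1 in spleen (0 shared) and 0 for the difference. Without both doubtful arrays there were 5 in thymus (2 shared), 2 in spleen (1 shared) and 0 for the difference, and with a sex covariate and without WT replicate 22 there were 1, 0 and 0. Arrays of a single tissue gave 0 in thymus and 0 in spleen, with or without replicate 28. An unadjusted p under 0.05 with a fold of at least 1.5 gave 42 in thymus, 27 in spleen, 40 for the difference and 3756 for the WT populations (3745 shared), whose count was otherwise 6996 to 12840. Fits with fewer arrays or more terms have fewer residual degrees of freedom; beyond that, the cause was not tested.

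Leaving out each array in turn gave 1 to 14 genes in thymus, 0 to 3 in spleen, 0 to 5 for the difference and 8673 to 9205 for the WT populations. Where 1 thymus ENK KO array remained, it was assumed to vary like the other groups. The lists numbered 2 to 6 in thymus, 4 to 10 in spleen and 5 to 11 (without thymus WT replicate 38) for the difference, where 7 were called; without replicate 28 those added in spleen were mitotic genes, higher, and CD4 T cell markers and NF-kappaB genes, lower (adjusted p = 0.0471 each), the last also called without WT replicate 40 (0.00983) or 22 (0.016). An estimated correlation left 0 lists in thymus, 0 in spleen (also 0 without replicate 28, smallest adjusted p = 0.629) and 0 for the difference, and fry 0, 1 (0 without replicate 28, 0.0597) and 0. Without the 2-month-old animals 11 lists were called in spleen, with males only 11 and without both doubtful arrays 4. Both fits with 11 lists lost the opioid and immediate early calls. They added T lineage, T cell receptor, naive T cell and cholesterol synthesis genes, higher, and myeloid and NK cell markers, lower. Both fits keep replicate 28, the array with CD4+ T cell markers, and none of these added lists was called in the fit that leaves it out. Over these changes of arrays and covariates the largest adjusted p was 1.84e-09 for mitotic, 0.00158 for replication, 0.359 for heat shock and 0.235 for Notch genes in thymus. In spleen it was 0.0027 for erythroid and platelet, 0.0659 for B cell, 0.0981 for effector and memory, 0.927 for immediate early, 0.114 for antigen presenting, 0.106 for complex I and 0.177 for opioid genes.

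En2 differed by 0 to 0.13 in thymus and by -0.067 (without ENK KO replicate 31) to 0.37 in spleen. With an array of the same tissue left out, 97 of 105 values of the genes named in thymus (En2 aside) kept their side of the threshold, 2 lost and 6 gained it, and 182 of 189 in spleen, where 6 lost and 1 gained it; 0 of these changed direction. Ppbp also lost its call without any one thymus array (adjusted p = 0.0552 to 0.0594). With a sex covariate or without the 2-month-old animals, Ppbp lost its call (adjusted p = 0.053 and 0.342) and without those animals Rxfp1 in thymus gained one (-0.53, adjusted p = 0.022), while all 40 values of the WT populations kept theirs. Low signal limits what could be called for genes such as En2. In simulated data the thymus design recovered 95% of genes changed by a log2 value of 1 and 73% of those changed by 0.5. Smaller differences were thus missed more often in this design, and other numbers of arrays were not simulated. These shares hold for 200 genes changed at once and may be too high where few genes change. In the thymus data Gnb4 at -1.45 and Plekhf1 at -1.20 did not pass (limma adjusted p = 0.168 and 0.0884).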

Other observations

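Of the tests in this part, that of the neighbours of En2 was chosen only after the result was seen. Other splits of the samples were planned.

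Several other gene lists were higher in WT spleen CD8+ cells than in WT thymocytes. NF-kappaB pathway genes were higher in 13 of 18 and lower in 0, with Traf1 at 2.50 and Bcl3 at 2.01 (adjusted p = 0.000607; adjusted p = 0.426 with an estimated correlation). Immediate early and activation genes were higher in 15 of 26 and lower in 1, with Myc at 3.02 and Junb at 2.27 (0.00389; adjusted p = 0.578 with an estimated correlation). Glycolysis genes were higher in 11 of 16 and lower in 2 (0.00646), cytokine receptor and STAT genes higher in 14 of 23 and lower in 5 (0.0228) and heat shock genes higher in 9 of 17 and lower in 1 (0.0319), with adjusted p = 0.384, 0.431 and 0.531 with an estimated correlation. Markers of other cell types were higher in spleen as well: B cell markers in 10 of 16 with 1 lower (0.0228), with Ms4a1 at 2.06 and Bank1 at 2.29, antigen presenting cell markers in 9 of 13 with 1 lower (0.00646) and myeloid markers in 11 of 19 with 2 lower (0.0376), with adjusted p = 0.58, 0.431 and 0.531 with an estimated correlation. Adjusted over the list alone these counts did not move.

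Srpk2, higher in ENK KO thymocytes, lies on the same chromosome as En2, with 33 tested genes between them in the GRCm38.p6 gene order. DNA of another strain flanking a targeted En2 locus could carry variants that alter its neighbours. Of the 99 tested genes nearest En2, without Srpk2, 1 had an unadjusted p under 0.01 in thymus (1.01%), against 0.879% of the 13532 others (Fisher's exact one-sided p = 0.585). An excess among the neighbours was thus not seen, and an effect on Srpk2 alone stays open. The labels give 1 strain for all animals and do not say how the mice were made.

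Other splits of the 9 spleen arrays into groups of 4 and 5 gave as many changed genes as the real one in 17 of 100 splits drawn, the real one included. The real count was 1 and the highest other 55, so chance cannot be excluded for the count of genes. A split with that many genes may point to a structure of the samples other than genotype, which was not tested. On the third principal component (2.47% of the variance) the spleen WT arrays lay at -8.62 to -0.45. Spleen ENK KO replicates 3, 6 and 28 lay at 13.1, 8.24 and 11.5, and replicates 31 and 25 at -6.84 and -1.53. Replicates 3 and 6 are the 2-month-old animals, labelled female. In thymus, replicates 1 and 7, labelled female, lay at 8.14 and 6.57, the others at -7.30 to -4.04. This component thus overlaps in part with genotype, age and sex. For spleen lists 47 of 100 splits gave as many, with 7 in the real split and up to 15 in others, so chance cannot be excluded there either. For the WT populations 1 of 35 splits, the real one, gave as many genes (9362, highest other 6361). That is the smallest share that 35 splits can give (2.86%), so this test cannot exclude chance. The real split also sets spleen cells against thymus cells, so that its rank could be foreseen. The thymus comparison has 2 arrays in a group and was not tested in this way.

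Thymus arrays shared many values to the last digit. All 3 thymus WT arrays had 1 value for 11.6% of the tested genes, against 0.345% for the 4 spleen WT arrays, and a median of 27.0% of values were identical between any pair of thymus arrays, against 6.64% in spleen. For 5.48% of tested genes the thymus difference was 0 to within 1e-09. The cause of the shared values was not tested. Tied values have no spread, and the thymus arrays enter the spread shared by all comparisons. Whether thymus and spleen arrays were normalized together is not given, so the differences between WT populations may compare values set on separate scales. Across the 13641 genes, which are not independent replicates, the thymus and spleen differences had a Pearson correlation of 0.196.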
